A study of Homo sapiens with 6 samples.

How the data were processed

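The 6 arrays are of Agilent's human 4-pack gene expression design 026652. Per the labels' protocols, 100 ng of total RNA was amplified with T7 priming and labelled with Cy5. Images were quantified with Agilent Feature Extraction 10.7.3.1, per the submitters' processing notes and the file headers. Per the file headers, 2 channels were scanned under the protocol GE2_107_Sep09, made for arrays hybridised in both colours, but the deposited files hold the red (Cy5) columns only; what the green channel held is not given in the sources used here. The red processed signal is an intensity on a linear scale that Feature Extraction had background-subtracted and dye-normalized with the other channel, per the file headers. The linear dye factors in the headers were between 1.73 and 2.48. The deposited series table held the same intensity: its values equalled the red processed signal for all 44495 features within a relative tolerance of 1e-06, on a linear scale and without centring, with column medians of 165, 165, 157, 152, 169 and 154.

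Spots flagged as outliers (279 to 436 per array) and control spots were left out, and saturated spots (1 or 2 per array) were kept. The log2 of the deposited intensity minus the array's 75th percentile was averaged over the spots of a probe, which gave 34127 probes from 43118 spots. A probe was tested if it was well above background on all arrays of at least 1 group, which left 22464. Where the probe was not well above background on any array of a group, the fold is a bound: the brighter group's mean against the mean of, per array, the higher of the lowest signal among probes well above background and the dim probe's own. There were 184 such tested probes in sponge-LV, of which 79 passed the threshold, and 11 in sponge-sh30a-5p, of which 10 passed. The 75th percentile of the signal was between 1020 and 1090 on the 6 arrays. Spots of 1 probe differed by an SD of 0.05 to 0.07 on the log2 scale over 733 probes printed 10 times, and the smallest SD of the difference between arrays of a group was 0.32, so none was counted as a duplicate.

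Probes were named by their RefSeq accession, without versions, through a gene table of assembly GRCh38.p14. The file headers name the build GRCh37, so no coordinates are given. Of 34127 probes 25863 carried a RefSeq accession and 24910 matched a gene, together 19102 genes; probes without a match, among them 123 higher and 106 lower at the threshold, are unnamed here. A gene's value is that of its brightest tested probe, and 3181 genes had more than 1 tested probe. Among the genes named by the rule or in the text, SEPTIN7, PIK3CD, LYPLA1, RFC3, H2AC6, CEACAM1, KIF3C, SRSF10 and EEF1A1 had probes that differed in whether they passed.

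The groups were compared with limma 3.58.1 (lmFit and eBayes, two-sided) in R 4.3.3 with Benjamini-Hochberg adjustment over all tested probes and a threshold of 0.05. The 22 gene lists were tested with camera at a preset correlation of 0.01 and again with an estimated one, adjusted over the 22 lists. Intervals of list medians are 95% bootstrap intervals over genes (10000 resamples). They treat the genes of a list as independent and leave out the spread between arrays, so they are not intervals of the group difference. The design, the lists, the rule for named genes and most alternatives were fixed before the data were examined. The rule names the 10 largest rises and 10 largest falls among genes past the threshold, well above background on all 6 arrays and with groups that did not overlap; DTL, CDKN1A and 1 further gene; up to 4 members of each list with the smallest p; and the 3 largest bounds in each direction. Uncharacterised loci are skipped, and some genes that the rule names are not reported here.

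On simulated data with 50 changed probes of each size among 22448, the limma comparison of sponge-sh30a-5p with sponge-LV recovered 4% of changes of 0.5 on the log2 scale, 58% of changes of 1, 90% of changes of 1.5 and 92% of changes of 2, and 5 of 127 calls (3.9%) were false. The real comparison gave 2553 calls, and the adjustment is less strict where more probes pass. The recovery rates therefore do not carry over to the real comparison. For the list test, 200 lists with no shift gave an unadjusted p under 0.05 in 2% of cases at the preset correlation and in none with an estimated correlation. Simulated probes varied independently of each other and without a slide effect. These rates were therefore not tested for lists of correlated genes, such as the histones, with an estimated correlation of 0.89.

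Alternatives were normexp background correction, quantile and median scaling, no filter or a stricter filter on dim probes, outlier spots kept, eBayes with trend and robust, the slide as a block, the replicate number as a block, the deposited series table, unmoderated tests, a fold minimum of 1.5, the mean over a gene's probes and each array left out. The files used here hold no red mean signal, so normexp was run on the red median signal and its background. Added after seeing the data were the background-subtracted intensity before dye normalization (floor of 5), slide 1 alone, and 2 shortened gene lists. Where slide 1 was taken alone, the single sponge-sh30a-5p array was assumed to vary like the sponge-LV arrays. A planned test of transcripts with a miR-30a-5p seed site was not run, because no 3' UTR sequences were used here. Figures were drawn with matplotlib.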

Results

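Messenger RNA was measured in HCT116, an established human colon carcinoma cell line that is widely used to study the cell cycle and p53. The 6 samples form 2 groups of 3: cells with the vector labelled sponge-LV and cells with the vector labelled sponge-sh30a-5p. The series title says that the cells overexpressed the microRNA miR-30a-5p, whereas "sponge" commonly names a transcript that sequesters a microRNA. The labels do not settle which of these the second vector did, so differences are given as sponge-sh30a-5p minus sponge-LV. The series design calls the samples biological replicates without saying what separated them, and the p-values measure the spread between these samples. Each sample was hybridised to 1 array with 34127 non-control probes. In the sponge-LV arrays 65%, 66.7% and 67.1% of the probes lay well above background, and in the sponge-sh30a-5p arrays 72.8%, 70.1% and 65.3%. The number of arrays limits the precision. The arrays lay on 2 slides: slide 1 held the 3 sponge-LV arrays and sponge-sh30a-5p replicate 1, and slide 2 held sponge-sh30a-5p replicates 2 and 3. A fit with the slide as a block therefore took its difference from slide 1, and no comparison was possible within slide 2. Values are log2 signals relative to the 75th percentile of the array, and 22464 probes naming 14192 genes were tested with limma and Benjamini-Hochberg adjustment.

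The question of the comparison was how the transcriptome of these cells differed with the miR-30a-5p vector. DTL, the substrate receptor of the CRL4-CDT2 ubiquitin ligase, had the largest fall among the genes that met the naming rule, and most listed genes of DNA replication and mitosis fell with it. Most listed histone genes also fell, but as a list they did not pass with an estimated correlation (adjusted p = 0.487, against 0.0302 for each of the other 2 lists). Among the genes that met the naming rule, CDKN1A, which encodes the cyclin-dependent kinase inhibitor p21, and INS, which encodes insulin, had the largest rises. Each was measured by 1 probe. Of the 22464 probes, 1332 were higher and 1221 lower in sponge-sh30a-5p cells, together 11.4%, which came to 896 genes higher and 901 lower by their brightest probe. Changes of at least 2-fold were more often falls, with 292 probes lower and 112 higher. The groups did not overlap for 7769 of 22448 probes measured on every array (34.6%, where chance gives 10%). The first principal component held 50% of the variance and separated the groups. With the slide as a block, 125 probes were higher and 556 lower, and within slide 1 alone 186 were higher and 634 lower. Of the 77 named genes that passed, 36 lost the call with the slide as a block. All 36 kept their sign, with changes there of 0.90 times those over all arrays (median), while their median standard error grew from 0.15 to 0.20. The slide fit reuses the slide 1 arrays, so a kept sign is not separate evidence. Where the groups did not overlap, the sign could not change. Leaving out 1 array gave 208 probes higher and 459 lower without sponge-LV replicate 1, 140 and 362 without sponge-LV replicate 2, 1203 and 919 without sponge-LV replicate 3, 1093 and 1430 without sponge-sh30a-5p replicate 1, 519 and 748 without sponge-sh30a-5p replicate 2, and 519 and 757 without sponge-sh30a-5p replicate 3.

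**Figure D1:**
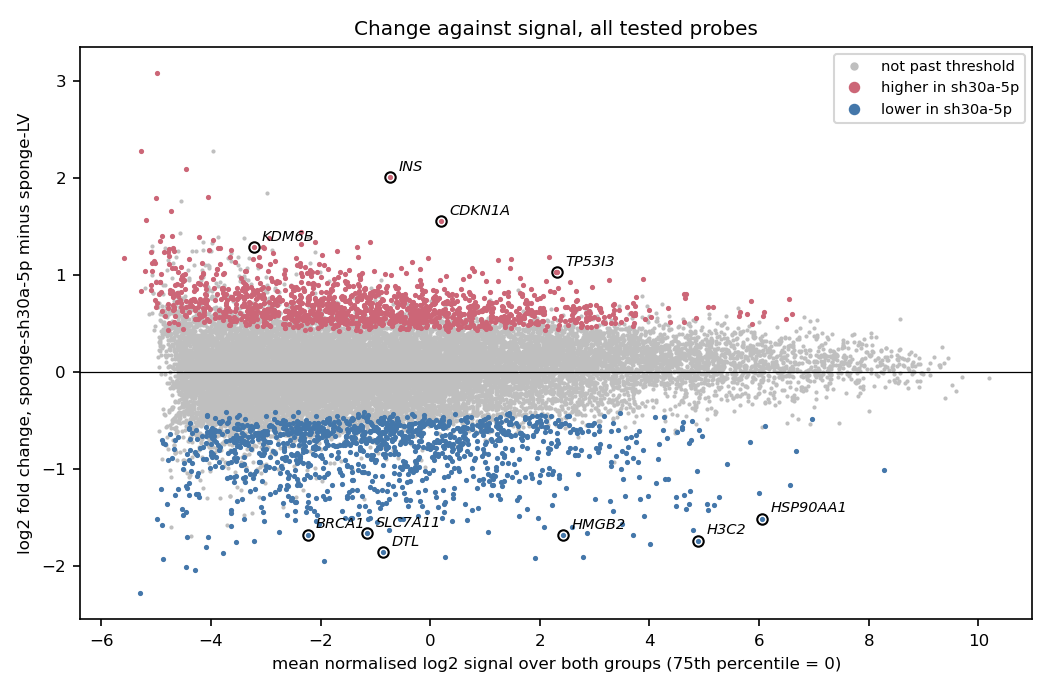
Each point is 1 of the 22464 tested probes; the horizontal axis is the mean log2 signal relative to the 75th percentile and the vertical axis the log2 fold change, sponge-sh30a-5p minus sponge-LV. Red points are the 1332 probes higher and blue points the 1221 probes lower at the threshold, and circles mark 10 named genes, among them DTL at -1.85 and INS at 2.00.

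DTL has been reported as a target of miR-30a-5p in colon carcinoma, and that report may rest on these same arrays, so its direction here is not independent evidence. Its normalised log2 signal was 0.06 ± 0.20 (SD, n = 3) in sponge-LV cells and -1.79 ± 0.04 (SD, n = 3) in sponge-sh30a-5p cells. The difference was 3.61-fold lower (95% interval 2.92 to 4.47; limma adjusted p = 0.00154). Within slide 1 the log2 change was -1.89 (adjusted p = 0.00746), and with the slide as a block the adjusted p was 0.014. No probe matched the precursor of miR-30a, and the probe of its host gene LINC00472 was not well above background on any array, so the arrays gave no direct reading of the vector's own product.

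CDKN1A rose from -0.58 ± 0.10 to 0.98 ± 0.18 (SD, n = 3 per group), 2.93-fold (95% interval 2.37 to 3.64; limma adjusted p = 0.00156). It changed by 1.49 within slide 1 (adjusted p = 0.00949) and kept an adjusted p of 0.0144 with the slide as a block. CDKN1A protein and the replication licensing factor CDT1 are known substrates of the ligase to which DTL belongs. The arrays measured messenger RNA and not protein, so the changes of these genes do not show whether the activity of the ligase changed. Of the 14 measured genes of the CRL4-CDT2 ligase and its substrates, 5 fell, 1 rose and 8 did not pass, and the counts were the same when adjusted over the list alone. Beside DTL, the falls were CDT1 (-1.10 ± 0.17, log2 change ± SE), CHEK1 (-0.84 ± 0.14), PCNA (-0.86 ± 0.14) and E2F1 (-0.83 ± 0.15), of which PCNA and E2F1 were singled out after their values were seen. CDT1, PCNA and E2F1 also belong to the G1/S and DNA replication list below, so their falls are counted in both lists. The ligase subunits DDB1 (0.24 ± 0.15), RBX1 (-0.14 ± 0.13), CUL4A (0.10 ± 0.17) and CUL4B (0.03 ± 0.17), singled out after their values were seen, did not pass. CDT1 (-0.90 ± 0.22, adjusted p = 0.0763) and E2F1 (-0.63 ± 0.19, adjusted p = 0.113) lost the call with the slide as a block. The list as a whole did not pass camera (median -0.06, adjusted p = 0.0918, or 0.487 with an estimated correlation). At the preset correlation it did pass with the slide as a block (median -0.18, adjusted p = 0.0337), within slide 1 (adjusted p = 0.0309) and without sponge-sh30a-5p replicate 3 (median -0.10, adjusted p = 0.0369).

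**Figure D2:**
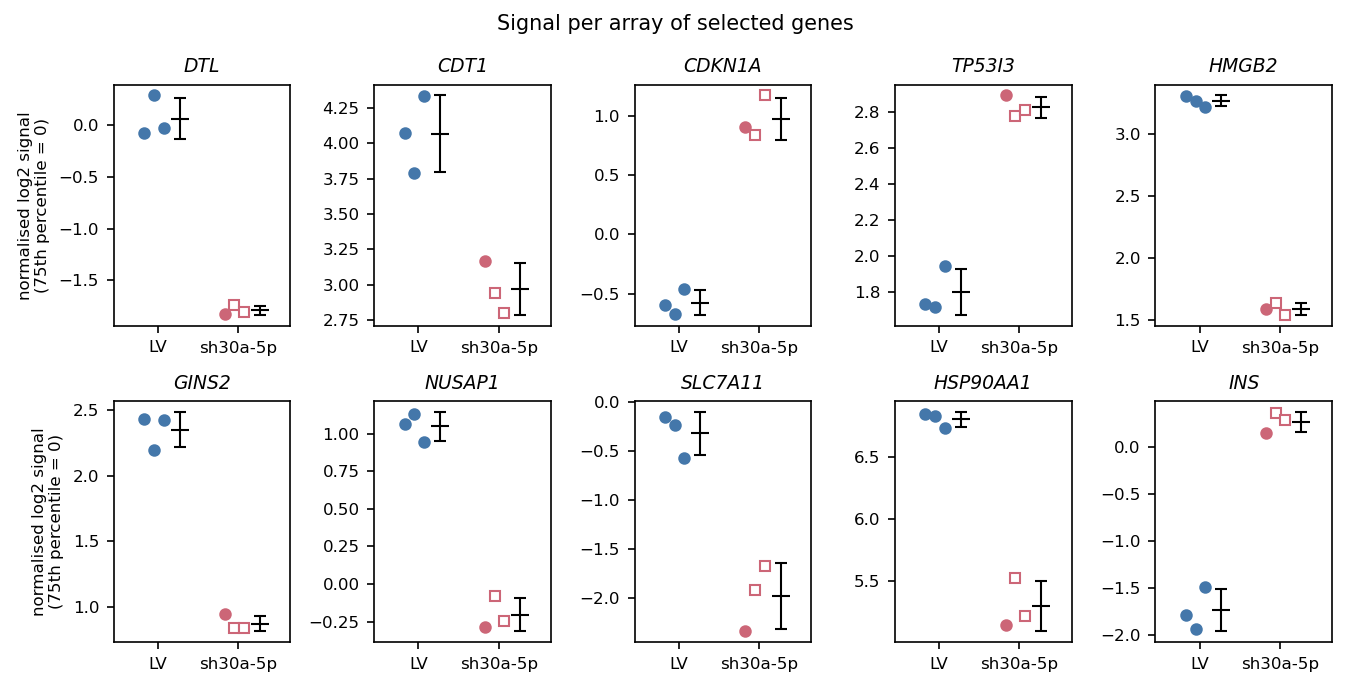
Normalised log2 signal of 10 genes on each array, with the 75th percentile of the array at 0; filled circles are arrays on slide 1, open squares arrays on slide 2, and the black bars show the mean ± SD of each group of 3. In none of these genes did the groups overlap, and the vertical axes differ between panels and do not start at a common level.

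Genes of the G1/S transition and DNA replication fell together. Of 36 measured members 32 fell, none rose and 4 did not pass (34 fell when adjusted over the list alone), and the list's median log2 change was -1.0 (95% bootstrap interval -1.09 to -0.86). The DNA polymerase clamp loader subunit RFC4 fell by 1.41, the GINS helicase complex subunit GINS2 by 1.48, the cohesion factor DSCC1 by 1.51 and the exonuclease EXO1 by 1.43 on the log2 scale, with standard errors of 0.12, 0.12, 0.14 and 0.11. The 4 members that did not pass, singled out after their values were seen, were SLBP (-0.44), CCNE1 (-0.27), CDC6 (-0.27) and RFC3 (-0.39). The list passed camera with the preset correlation (adjusted p = 4.29e-29) and with an estimated correlation (adjusted p = 0.0302). Its median was -1.06 both within slide 1 and with the slide as a block (adjusted p = 2.83e-28), where 25 of the 32 kept the call.

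Genes of G2/M and mitosis fell in the same cells. Of 34 measured members 24 fell, none rose and 10 did not pass (30 fell when adjusted over the list alone), with a median of -0.81 (95% bootstrap interval -1.0 to -0.60). Examples were the mitotic kinase NEK2 (-1.31 ± 0.15), the spindle protein NUSAP1 (-1.25 ± 0.12), the kinesin KIF23 (-1.19 ± 0.12) and the spindle checkpoint kinase BUB1B (-1.0 ± 0.12; log2 change ± SE). The list passed camera with the preset correlation (adjusted p = 9.48e-22) and with an estimated correlation (adjusted p = 0.0302), and its median was -0.91 with the slide as a block and within slide 1 (block adjusted p = 2.87e-21); 18 of the 24 kept the call with the block.

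Over all arrays, replication-dependent histone genes had the largest median fall of the 22 lists. With the slide as a block and within slide 1 their median was -0.81, a smaller fall than those of the G1/S and G2/M lists. Of 20 measured members 18 fell and 2 did not pass, with the same counts adjusted over the list alone. Of the 18 falls, 5 kept the call with the slide as a block and 13 lost it, and the changes of these 13 were 0.71 times those over all arrays (median), with a median standard error of 0.20 against 0.19. The list's median over all arrays was -1.14 (95% bootstrap interval -1.36 to -1.0; camera adjusted p = 2.01e-14), with an adjusted p of 0.487 at the estimated correlation of 0.89. That interval is over genes, leaves out the spread between arrays and does not hold the slide 1 median. H3C2 fell by 1.74, H2AC6 by 1.60, H2AC4 by 1.5 and H2BC4 by 1.13 on the log2 scale. H1-5 (0.35 ± 0.20) and H2BC6 (0.05 ± 0.19), singled out after their values were seen, did not pass. The list passed with the slide as a block at the preset correlation (adjusted p = 1.86e-10), and H3C2 changed by -1.23 within slide 1. Histone genes are close in sequence, and a probe can take up transcripts of its paralogs. Whether the T7-primed labelling took up all histone transcripts alike was not tested, so these values may not stand for the whole of the histone messenger RNA.

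The other named falls were FAM111B, a serine protease gene, at -1.75 ± 0.18, the zinc finger gene ZNF367 at -1.69 ± 0.20, the chromatin protein gene HMGB2 at -1.67 ± 0.11, BRCA1, a DNA repair gene, at -1.67 ± 0.14, the cystine transporter gene SLC7A11 at -1.66 ± 0.19 and the cohesin acetyltransferase gene ESCO2 at -1.65 ± 0.22 (log2 change ± SE). With the histone genes H3C7 (-1.67 ± 0.23) and H3C10 (-1.65 ± 0.24) and those given above, these were the 10 largest of 866 falls that met the naming rule, and their adjusted p lay between 0.00154 and 0.00603. H3C10 changed by -1.23 ± 0.27 with the slide as a block (adjusted p = 0.0573) and the other 9 stayed under the threshold there. ZGRF1, BRIP1 and GPR19 were not well above background on any sponge-sh30a-5p array and were at least 3.32-fold, 3.15-fold and 2.55-fold lower there (adjusted p = 0.00154, 0.00337 and 0.00292). BRIP1 encodes a helicase that partners BRCA1.

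INS rose from -1.74 ± 0.23 to 0.27 ± 0.11 (SD, n = 3 per group), 4.01-fold (95% interval 3.18 to 5.06; adjusted p = 0.00154; 1.89 within slide 1 and adjusted p = 0.014 with the slide as a block). After INS and CDKN1A came SDCBP2 (1.44 ± 0.29), the phosphatidylserine decarboxylase gene PISD (1.34 ± 0.21), the orphan nuclear receptor gene NR6A1 (1.32 ± 0.17), the histone H3K27 demethylase gene KDM6B (1.29 ± 0.17), LINC00028 (1.27 ± 0.19), the homeobox gene ISL2 (1.23 ± 0.17), the glucosylceramidase gene GBA2 (1.18 ± 0.18) and the small heat shock protein gene HSPB8 (1.18 ± 0.19). These were the 10 largest of 812 rises that met the naming rule. INS was measured by 1 probe, and whether that probe took up other transcripts was not tested. SDCBP2 (1.79 ± 0.38), PISD (1.18 ± 0.29), GBA2 (1.0 ± 0.24) and HSPB8 (1.07 ± 0.27) lost the call with the slide as a block (adjusted p = 0.0533, 0.0763, 0.0705 and 0.0774). Their standard errors were larger there. The change of SDCBP2 was larger and those of PISD, GBA2 and HSPB8 were smaller. UNC5C, OR11G2 and KALRN were not well above background on any sponge-LV array and were at least 2.74-fold, 2.10-fold and 1.87-fold higher in sponge-sh30a-5p cells (adjusted p = 0.043, 0.0269 and 0.00848); the sponge-sh30a-5p signal of UNC5C had an SD of 1.76.

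Of 32 measured target genes of p53, 12 rose, none fell and 20 did not pass; adjusted over the list alone, 17 rose and 1, PMAIP1 at -0.43, fell. The median was 0.45 (95% bootstrap interval 0.23 to 0.63; camera adjusted p = 5.5e-06 at the preset correlation and 0.487 with an estimated one). Of the 12 rises, 4 kept the call with the slide as a block. The 8 that lost it kept their sign, with changes 0.74 to 1.2 times those over all arrays and a median standard error of 0.23 against 0.17. Beside CDKN1A, TP53I3 rose by 1.03 ± 0.12, the antiproliferative gene BTG2 by 0.94 ± 0.12 and the decoy death receptor gene TNFRSF10C by 0.86 ± 0.12 (log2 change ± SE). MDM2, the p53 ubiquitin ligase and a textbook p53 target, did not pass with any of its 3 probes (-0.14 ± 0.12 for the brightest, 0.49 ± 0.18 and 0.28 ± 0.19 for the others); it was singled out after its value was seen. The list's median was 0.45 with the slide as a block and within slide 1. In these slide fits the median of all tested probes was 0.12, against 0.03 over all arrays. An unchanged list median is therefore a smaller shift against all probes, and the slide medians of the other lists share this baseline.

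Of 54 measured genes reported as targets of the miR-30 family, 4 fell, 2 rose and 48 did not pass, with the same counts adjusted over the list alone, and the median was -0.13 (95% bootstrap interval -0.27 to -0.04; camera adjusted p = 0.0198 at the preset correlation). The adjusted p was 0.493 with an estimated correlation, 0.0795 without the filter on dim probes and 0.11 without sponge-sh30a-5p replicate 1. The falls were DTL, the cyclin gene CCNE2 (-1.23 ± 0.14), the septin gene SEPTIN7 (-0.75 ± 0.14) and LYPLA1 (-0.85 ± 0.19), and the rises were the phosphoinositide 3-kinase gene PIK3CD (0.61 ± 0.14) and TMED3 (0.55 ± 0.14). LYPLA1, which passed with 1 of its 2 probes, and TMED3 were singled out after their values were seen. SEPTIN7 (-0.69 ± 0.20, adjusted p = 0.109), PIK3CD (0.64 ± 0.20, adjusted p = 0.121) and TMED3 (0.66 ± 0.19, adjusted p = 0.109) lost the call with the slide as a block, at similar changes and larger standard errors. With the slide as a block and within slide 1 the list's median was -0.20 (block adjusted p = 0.00178).

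Of 27 measured genes of the unfolded protein and integrated stress responses 7 fell, 2 rose and 18 did not pass (8 fell and 2 rose when adjusted over the list alone), with a median of -0.30 (95% bootstrap interval -0.45 to -0.04; camera adjusted p = 0.00222). The adjusted p was 0.493 with an estimated correlation. The largest of these falls were those of SLC7A11, CHAC1 (-1.17 ± 0.18), MTHFD2 (-0.86 ± 0.12) and the asparagine synthetase gene ASNS (-0.68 ± 0.12). SESN2 (0.66 ± 0.14) and DDIT4 (0.63 ± 0.15), singled out after their values were seen, rose. The list's median was -0.27 with the slide as a block and within slide 1 (block adjusted p = 0.00158), and 2 of the 9 calls were kept with the block. CHAC1 (-0.81 ± 0.20), ASNS (-0.61 ± 0.17), SESN2 (0.63 ± 0.21) and DDIT4 (0.60 ± 0.22) were among those lost (adjusted p = 0.0719, 0.101, 0.138 and 0.168). Of 14 heat shock genes 2 fell, 1 rose and 11 did not pass, the same as adjusted over the list alone. The chaperone gene HSP90AA1 fell by 1.51 ± 0.14, with all 3 of its probes lower, and HSPH1 fell by 0.95 ± 0.14, while the rise of BAG3 was at the threshold (0.82 ± 0.22, adjusted p = 0.05; 0.67 ± 0.32 and 0.241 with the slide as a block). The list did not pass (median -0.17, adjusted p = 0.09, or 0.543 with an estimated correlation), but did at the preset correlation with the slide as a block (median -0.12, adjusted p = 0.0464), with quantile normalization (0.0478), without sponge-LV replicate 1 (0.0358), without sponge-sh30a-5p replicate 3 (0.0176) and on signal taken before dye normalization (0.0468). Within slide 1 its adjusted p was 0.0575.

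Of 28 measured genes of hypoxia and glycolysis 9 rose, 1 fell and 18 did not pass (14 rose and 2 fell when adjusted over the list alone), with a median of 0.36 (95% bootstrap interval 0.23 to 0.51; camera adjusted p = 0.000643). The adjusted p was 0.543 with an estimated correlation. Examples were the aldolase gene ALDOC (0.97 ± 0.16), NDRG1 (0.96 ± 0.19), the adrenomedullin gene ADM (0.75 ± 0.14) and the glucose transporter gene SLC2A1 (0.71 ± 0.14). None of the 10 calls was kept with the slide as a block; the changes of these 4 genes there were 0.84 ± 0.22, 0.65 ± 0.23, 0.77 ± 0.20 and 0.69 ± 0.20 (adjusted p = 0.0878, 0.153, 0.0809 and 0.105). The hexokinase gene HK2, singled out after its value was seen, fell by 0.65 ± 0.15 (0.85 ± 0.20 and adjusted p = 0.0654 with the block), and VEGFA (-0.44) was the other member that fell when adjusted over the list alone. The list's median was 0.37 with the slide as a block (adjusted p = 0.0337) and within slide 1.

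Of 25 measured epithelial genes 4 rose, none fell and 21 did not pass (6 rose when adjusted over the list alone), with a median of 0.25 (95% bootstrap interval 0.03 to 0.42; camera adjusted p = 0.0194). The adjusted p was 0.543 with an estimated correlation and 0.0528 without sponge-LV replicate 1. The transcription factor gene ELF3 rose by 1.03 ± 0.14, SPINT1 by 0.79 ± 0.17, the splicing regulator gene ESRP2 by 0.56 ± 0.12 and RAB25 by 0.53 ± 0.13 (log2 change ± SE). ELF3 kept the call with the slide as a block (adjusted p = 0.0487), and SPINT1 (0.73 ± 0.24, adjusted p = 0.136), ESRP2 (0.56 ± 0.17, 0.12) and RAB25 (0.60 ± 0.18, 0.113) lost it with similar changes and larger standard errors. The list's median was 0.45 with the slide as a block and within slide 1, where the median of all tested probes was 0.12, against 0.03 over all arrays. Mesenchymal genes went both ways, with 2 of 21 higher, 2 lower and 17 not passing (4 and 4 when adjusted over the list alone). ITGA5 rose by 0.89 ± 0.12 and LOXL2 by 0.52 ± 0.13, and CALD1 fell by 0.63 ± 0.14 and CCN1 by 0.70 ± 0.16, of which LOXL2 (0.55 ± 0.18, adjusted p = 0.135) and CCN1 (-0.66 ± 0.23, adjusted p = 0.149) lost the call with the slide as a block. Their median was 0.05, their mean -0.01 and camera's direction was down (adjusted p = 0.826; median 0.12 within slide 1 and with the block).

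**Figure D3:**
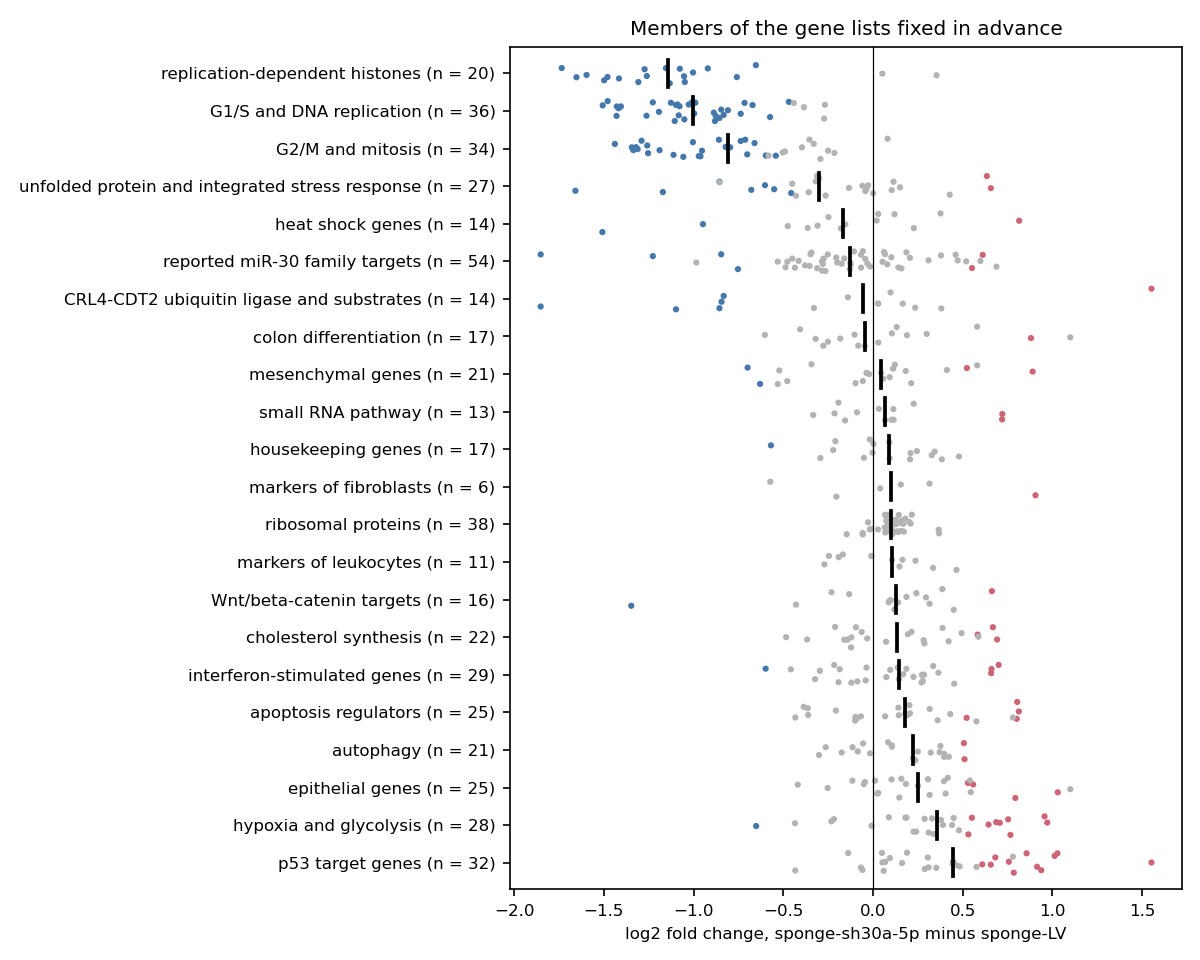
Log2 fold change, sponge-sh30a-5p minus sponge-LV, of each measured member of the 22 gene lists, with the number measured in brackets. Red and blue points are members higher and lower at the threshold, grey points did not pass, and black bars are list medians, which run from -1.14 for the histones to 0.45 for p53 targets.

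None of the remaining lists passed camera. Of 25 apoptosis regulators 4 rose and none fell (6 and 1, PMAIP1, when adjusted over the list alone): BAK1 (0.81 ± 0.15), the antiapoptotic gene BCL2L1 (0.80 ± 0.15), CASP9 (0.52 ± 0.12) and BMF, which was not well above background in sponge-LV cells and was at least 1.44-fold higher. Their median was 0.18 (adjusted p = 0.239; 0.11 within slide 1 and with the slide as a block). In the small RNA pathway AGO2 (0.72 ± 0.12) and TNRC6B (0.72 ± 0.16), which act in microRNA silencing, were the 2 of 13 that rose, and none fell (median 0.07, adjusted p = 0.815; 0.10 with the block and within slide 1). Of 29 interferon-stimulated genes 3 rose and 1 fell (3 and 2 when adjusted over the list alone, with HERC5 at -0.46), namely IRF9 (0.66 ± 0.13), TAP1 (0.70 ± 0.14), UBE2L6 (0.66 ± 0.15) and IFIT5 (-0.60 ± 0.16; median 0.14, adjusted p = 0.382; 0.22 with the block and within slide 1). Among 16 Wnt/beta-catenin targets the transcription factor gene MYB fell by 1.35 ± 0.13 and BMP4 rose by 0.66 ± 0.16 (median 0.13, adjusted p = 0.673; 0.09 with the block and within slide 1, where camera's direction was down). Of 22 cholesterol synthesis genes 3 rose and none fell, with STARD4 (0.69 ± 0.13) as an example (median 0.13, adjusted p = 0.32; 0.19 with the block and within slide 1). Of 21 autophagy genes ULK1 (0.51 ± 0.12) and GABARAPL1 (0.51 ± 0.13) rose (median 0.22, adjusted p = 0.119; 0.20 with the block and within slide 1); at the preset correlation the list passed with normexp background correction (adjusted p = 0.0426) and without the filter on dim probes (adjusted p = 0.0439), and over the main values its adjusted p was 0.543 with an estimated correlation. Of 17 colon differentiation genes CEACAM1 alone passed (0.88 ± 0.12), with a list median of -0.05, a mean of 0.06 and an adjusted p of 0.826 (median 0.14 with the block and within slide 1, where camera's direction was up). For the small RNA, Wnt, cholesterol, autophagy and colon lists the counts adjusted over the list alone were the same. With the slide as a block, MYB (adjusted p = 0.0144), IFIT5 (0.0435) and CEACAM1 (0.0428) kept the call, and the others that passed here lost it, with the same signs and with adjusted p from 0.0676 for BAK1 (0.88 ± 0.21 there) to 0.233 for GABARAPL1 (0.39 ± 0.18 there). PMAIP1 and HERC5 were singled out after their values were seen.

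None of 38 ribosomal protein genes passed on its own in limma, either over all probes or adjusted over the list alone, and the list median was 0.10 (95% bootstrap interval over genes, without the spread between arrays, 0.08 to 0.14; adjusted p = 0.215, or 0.87 at the estimated correlation of 0.82). The list median was 0.31 with the slide as a block and within slide 1, and 0.18 without sponge-sh30a-5p replicate 3. With the block (adjusted p = 0.000498) and without that replicate (adjusted p = 0.0176) the list passed camera at the preset correlation of 0.01, which is far below that estimate. The median of all tested probes was 0.12 in the slide fits against 0.03 over all arrays. Of 17 housekeeping genes TBP alone passed, also when adjusted over the list alone; it fell by 0.57 ± 0.13, and by 0.63 ± 0.18 with the slide as a block, where its adjusted p was 0.0982 (list median 0.09, adjusted p = 0.815; 0.17 with the block and within slide 1). Among markers of cells that a pure line should lack, none of 11 leukocyte genes passed over all probes or over the list alone (median 0.11, adjusted p = 0.815; 0.24 with the block and within slide 1). Of 6 measured fibroblast markers ACTA2, a smooth muscle actin gene, rose by 0.91 ± 0.13 (adjusted p = 0.0372 with the block), and THY1 at -0.57 fell when adjusted over the list alone (median 0.10, adjusted p = 0.679; 0.21 with the block and within slide 1).

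**Figure D4:**
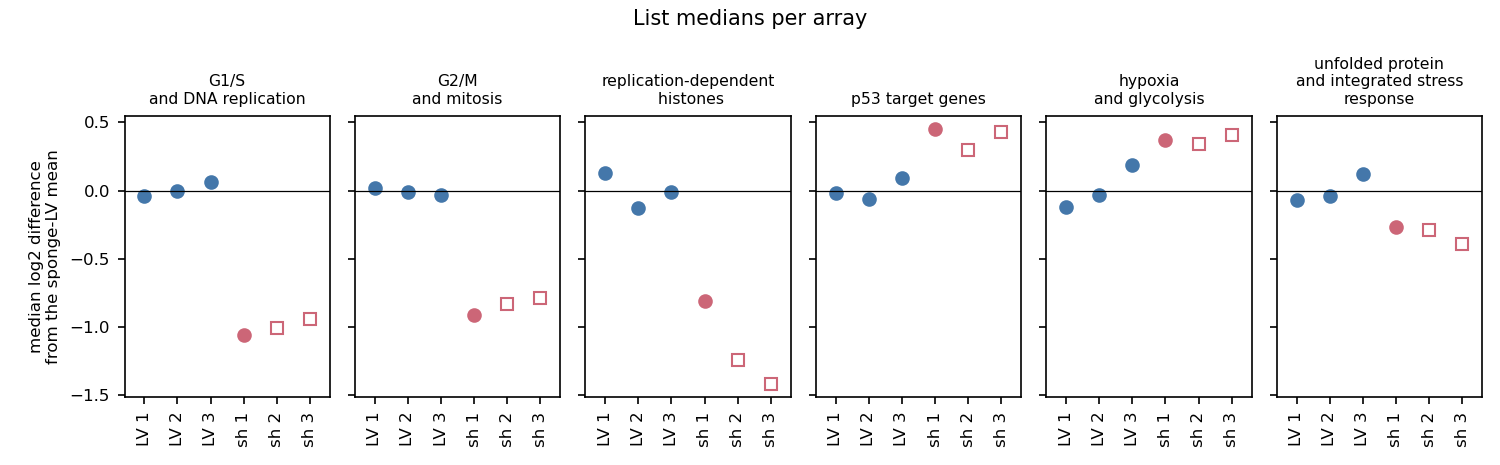
Median, over the members of 6 lists, of the log2 difference of each array from the sponge-LV mean; circles are arrays on slide 1 and squares arrays on slide 2, with sponge-LV in blue and sponge-sh30a-5p in red. The G1/S medians of the sponge-sh30a-5p arrays were -1.06, -1.01 and -0.94, and the histone medians were -0.81 on slide 1 and -1.24 and -1.42 on slide 2.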

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

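Alternatives chosen after seeing the data were the signal before dye normalization and slide 1 alone. No list or named gene that passed changed direction under any of the alternatives it was run in (lists were not run with the tests per probe or the 1.5-fold minimum), and 100% (rounded) of the 2553 calls kept their sign wherever they were tested, except under normexp, where 99.7% did. The alternatives reuse the same arrays, so a kept sign is not separate evidence. Where the groups did not overlap, the slide fits and the fits with 1 array left out could not change the sign. Counts of probes higher and lower moved by over 1.5 times under some alternatives. Without the filter on dim probes 167 were higher and 391 lower of 34127. With the slide as a block the counts were 125 and 556, of which 103 and 495 were among the main calls, and for slide 1 alone 186 and 634 (148 and 537 shared); in both the difference comes from the 4 arrays of slide 1. Unmoderated tests gave 77 and 175 (equal variance) and 1 and 9 (Welch). Leaving out each array in turn gave 140 to 1203 higher and 362 to 1430 lower. The balance of the calls did change: 52.2% were higher in the main setting, but 44% with normexp, 45.9% before dye normalization and 18.4% with the slide as a block. Other settings of scaling moved the median of all probes by at most 0.075 on the log2 scale. DTL kept its call in all 18 limma alternatives (log2 change -1.92 to -1.54, adjusted p 2.72e-05 to 0.0181) and under equal variance (adjusted p = 0.0295). DTL lost it with Welch's test at the same change of -1.85 (adjusted p = 0.134). With 3 arrays per group, the equal-variance and Welch tests share the change and its standard error and differ in their degrees of freedom. Welch's test passed only 1 probe higher and 9 lower in all, and CDKN1A also lost its call there (adjusted p = 0.118). The loss was therefore not particular to DTL. Of the lists, 3 passed as higher and 5 as lower; with an estimated correlation 0 passed as higher and 2 as lower. Of the named genes, 36 lost the call with the slide as a block, 31 without the filter, 74 with Welch's test and 7 to 32 with 1 array left out. A fit with the replicate number as a block (replicate block) gave 1094 probes higher and 1053 lower. The numbers were not taken as pairs: same-numbered arrays had correlated deviations of 0.102, 0.044 and 0.099, and sponge-LV replicate 1 correlated best with sponge-sh30a-5p replicate 2, at 0.167. Signal over background limits the dim probes, where changes can be given as bounds only. The seed-site tests, with all their alternatives of site definition, 3' UTR choice and length, were not run, as no 3' UTR sequences were used here.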

Other observations

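The symbol families, the fits on slide 1 alone and before dye normalization, the fits to list medians per array, the 2 shortened gene lists and the use of the G2/M list as a test of the G1/S fall were chosen after changes of single genes had been seen. The families were 168 groups of genes that share a letter stem and have at least 10 measured members. Families that passed camera as lower at the preset correlation were the genes with the stem MCM (8 of 10 lower, among them MCM8 at -1.38 ± 0.17, which no fixed list held), the CEP centrosomal genes (12 of 32 lower and 1 higher; CEP152 -1.17 ± 0.16, CEP55 -1.22 ± 0.16), the RAD recombination and repair genes (7 of 18 lower; RAD54L -1.36 ± 0.12) and the KIF kinesins (9 of 29 lower, KIF12 and KIF3C higher; KIF15 -1.44 ± 0.17). The genes with the stem MCM that did not pass were MCM3AP and MCM3AP-AS1, which share only the letters. Apart from MCM8, the lower MCM genes also belong to the G1/S list. Among the lower kinesins, KIF23, KIF11 and KIF2C also belong to the G2/M list. Nucleoporin genes with the stem NUP (7 of 22 lower; NUP107 -1.11 ± 0.14) and splicing factors with the stem SRSF (SRSF1 and SRSF10 lower of 11; SRSF1 -1.07 ± 0.17) also passed camera over the 168 families, with adjusted p = 0.00363 and 0.0148 against 2.25e-06 for CEP, 2.99e-06 for RAD, 1.14e-05 for MCM and 0.000206 for KIF. Of 17 KDM lysine demethylases 3 rose, KDM6B, KDM4B (0.59 ± 0.14) and KDM5B (0.52 ± 0.13), none fell and 14 did not pass (family adjusted p = 0.0203 at the preset correlation). No family passed with an estimated correlation (smallest adjusted p = 0.667). The medians of these 7 families kept their sign under normexp, quantile and median scaling and before dye normalization. The ZSCAN zinc finger genes, with 7 of 15 higher and none lower (median 0.40), did not pass as a family (adjusted p = 0.0701).

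The first pattern is the fall of the G1/S list. Within slide 1 its median was -1.06 (95% bootstrap interval over genes -1.16 to -0.94), below the bound of -0.25 that was set, after changes of single genes had been seen, for a slide effect as the whole cause. A fit to the list's median on each array with the slide as a block, which carries the spread between arrays, gave -1.07 (95% interval -1.26 to -0.87). This argues against a slide effect as the whole cause, but both values rest on 1 sponge-sh30a-5p array, which is assumed to vary like the others. Before dye normalization the median was -1.05 (-1.15 to -0.89 over genes, -1.16 to -0.93 over arrays), which argues against dye normalization with the green channel as the cause. A smaller share of cells in cycle would also lower G2/M genes, and their median of -0.81 (-1.0 to -0.60) is consistent with that hypothesis. Arrest at one stage, slower passage or a direct effect on transcription stays open, since arrays of whole cultures give no cell counts.

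The second pattern is the rise of CDKN1A. If a broad activation of p53 were its source, the other p53 targets should have a median above 0.25 with the interval also above it; the list without CDKN1A had a median of 0.44 (95% bootstrap interval 0.19 to 0.61), with 11 of 31 members higher and none lower. The interval reaches below the bound, so activation of p53 and a CDKN1A rise by other routes cannot be told apart here, and the list without CDKN1A had an unadjusted p of 4.61e-06 at the preset correlation and 0.0771 with an estimated one. CDKN1A lay higher in each sponge-sh30a-5p array than in any sponge-LV array.

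The third pattern is whether the second vector raised or sequestered the microRNA. Overexpression predicts lower and sequestration higher targets. Without DTL and members of the cell cycle lists, 52 reported miR-30 targets had a median of -0.13 (95% bootstrap interval -0.26 to -0.03), with 2 higher and 2 lower. Their camera p was 0.032 at the preset correlation and 0.266 with an estimated one, so overexpression and sequestration cannot be told apart on this list, although the direction is that of the series title. Seed-site tests, which would draw on many more genes, were not run.

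The comparison itself was set against other groupings of the arrays. The real split gave 2553 probes past the threshold and the highest of the other 9 splits gave 0, and 1 of the 10 splits, the real one, gave as many; 10 splits are too few for a share under 0.05.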
